A study of Psammomys obesus with 8 samples.

How the data were processed

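The analysis began from a table of read counts per contig that the authors deposited for 8 methyl-CpG capture libraries of sand rat hypothalamus, 4 low-low and 4 standard-low. Sequences were checked with FastQC and aligned with BWA, per the submitters' processing notes, and their versions, the assembler of the contigs and the genome build of the mouse matches are not given in the sources used here. Per the file headers and the contig names, each line held a contig, its sequence and 1 count per library, and for some contigs a mouse match with its position, the nearest mouse gene and the distance to it. The deposited counts were whole numbers and were used unscaled, with no estimate of fragment length or copy number. The lowest summed count was 81, so the deposited table holds only contigs above some minimum, and a low or zero value in a group was seen only where the other libraries held counts. Reads that map equally well to several repeat copies are placed by the aligner, and how the authors treated them is not given in the sources used here.

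Libraries were assigned to groups and replicate numbers by the labels. The header line separates the 8 library names by spaces and the values below it by tabs, so columns were matched to names in the order of the header, and every value per library rests on that order. The labels number the libraries as replicates of a group without saying that each came from a separate animal, father or litter, so p-values measure only the spread between these samples, which may in part be technical. Of the 548060 contigs, 208288 (38%) had a mouse match, 125082 lay inside a mouse gene by that match, and these represented 19098 genes. Gene names come from the table and rest on similarity to mouse, not on a sand rat annotation, and coordinates are the mouse positions of the table. The position of a match within exons or introns was not analysed here.

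Contigs were tested with edgeR 4.0.16 in R 4.3.3, with TMM factors, default glmQLFit settings and a two-sided glmQLFTest of standard-low against low-low, and Benjamini-Hochberg adjustment over all contigs at a threshold of 0.05. A filter at a mean of 10 counts per library was set, and it removed no contig. The groups, tests, gene lists, marker lists, rule for named contigs and most alternatives were chosen before the data were examined, and those added later are named as such. The rule named the 12 contigs with the largest positive and the 12 with the largest negative log2 fold change among those past the threshold whose 4 libraries of one group all lay above the 4 of the other in CPM, with neighbours within 1 kb counted once, and 8 fixed genes whatever their result (Pomc, Npy, Agrp, Lepr, Mc4r, Insr, Igf2 and Dnmt3a), each read at its most abundant contig. CPM values of single contigs and of genes were counts divided by the library total times the TMM factor. Summed CPM of a kind of contig per library, such as a repeat family, used the library total alone. Means carry SD over 4 libraries. A fold against a group without counts was computed against a floor of 3 counts over the group, and ratios with 1 to 3 counts carry 95% counting intervals.

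Tandem repeats were contigs in which at least 50% of bases repeat at a period of at most 60 bases. The 37-base family is the set of tandem contigs with a best period of 35 to 38 bases. Primate Alu, alpha satellite and L1 ends and rodent B1 were found with BLAST 2.17.0 against short consensus sequences. Primate repeats needed 80% identity over at least 60% of the contig. B1 needed a match over at least 20% of the contig, with no bound on identity. Shares of kinds among called contigs were compared with the table by Fisher's exact test. Library measures were compared with two-sided exact permutation tests over the 70 relabellings of 8 libraries (scipy 1.17.1), with Benjamini-Hochberg adjustment over 10 measures.

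For the gene lists, the most abundant contig inside each gene stood for it in camera (preset correlation 0.01) and fry of limma 3.58.1, and counts within each gene were also summed and tested with edgeR using the factors of the contig table. The 8 gene lists held 224 genes, of which 189 had a contig inside. The 9 marker lists covered neurons, oligodendrocytes, astrocytes, microglia, endothelium, ependymal cells and tanycytes, pituitary, thalamus or cortex, and blood, and adjustment was made within each of these 2 families of lists.

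The test was checked on simulated counts drawn from the means and library sizes of the real contigs. With edgeR, 0% of contigs with a 1.5-fold change, 38% with a 2-fold change, 96% with a 4-fold change and 100% with a 16-fold change passed, with 2 of 547860 unchanged contigs called. The simulated spread depended on abundance alone, with no contig more variable than others of its abundance. These rates therefore do not carry over to repeat contigs with counts in some libraries and almost none in others. Alternatives were DESeq2 1.42.0, limma voom with and without cyclic loess, DESeq2 size factors, library size and upper quartile scaling, a higher count filter, a replicate block, the share of counts in the top 1% of contigs as a covariate, and leaving out each library. Added after the data were seen were offsets for CpG density and GC content, the gene sums, a term for or removal of the libraries numbered 1, lists from contigs at any distance, and removal of repeat contigs. Contrasts over fixed windows were not run, because the table is made of contigs.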

Results

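DNA methylation was profiled in the hypothalamus of male *Psammomys obesus*, the fat sand rat, a desert gerbil that is used as a model of diet-induced obesity and diabetes. Methylated DNA was enriched with MethylMiner, in which the methyl-CpG binding domain of MBD2 captures double-stranded fragments, and the captured DNA was sequenced. The 8 libraries fall into 2 groups of 4, all from offspring aged 16 weeks, called low-low and standard-low here after the group names in the labels. The deposited description names paternal diet as the difference between them, while the series title speaks of parental diet. The question was where hypothalamic methylation differed between offspring with these different family diets.

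The unit of measurement was the read count over an assembled contig, and 548060 contigs with a median length of 442 bases were counted. Totals over these contigs were 13109928, 13533441, 12528388 and 13101023 in low-low libraries 1 to 4, and 11646180, 11655822, 12156525 and 11766046 in standard-low libraries 1 to 4. The mean total was lower in standard-low by more than the spread between libraries (two-sided exact permutation p = 0.0286, the smallest value that 4 against 4 can give, and 0.19 after Benjamini-Hochberg adjustment over 10 library measures). These are sums over the listed contigs, not the sequencing depth of the libraries. The median contig had a mean of 17.4 counts per library. A count ratio of captured DNA reflects methylation together with the amount of the underlying sequence, and no input libraries were used here.

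Of the 147 contigs called between standard-low and low-low offspring at an edgeR adjusted p below 0.05, 57 belonged to a family of tandem repeats with a 37-base unit, whose summed counts had a ratio of group means of 1.03 (exact permutation p = 0.486). Contig 2716599 of this family reached 7.97 ± 2.75 CPM (read counts scaled to a common library total; SD, n = 4) in standard-low against 0.0764 ± 0.153 in low-low, a 104-fold difference (edgeR adjusted p = 2.55e-24) that did not pass with limma voom (adjusted p = 0.402) or voom after cyclic loess (0.23). Its 4 low-low counts all came from low-low 1, and without that library it was at least 103-fold higher against a floor of 3 counts over the group. Among contigs lying in a gene by their mouse match, a contig in Oxct2a, a member of the succinyl-CoA:3-ketoacid CoA transferase family of ketone body breakdown, was 1.76-fold lower in standard-low. A contig in Kcnj4, which encodes an inwardly rectifying potassium channel, was 3.48-fold lower, and one in Pcdha10, a clustered protocadherin of neuronal cell surfaces, was 2.17-fold lower. A contig in Havcr2, which encodes the immune receptor TIM-3, was 2.69-fold higher. The Kcnj4, Pcdha10 and Havcr2 contigs did not pass with DESeq2.

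In the edgeR quasi-likelihood test, 147 of the 548060 contigs passed an adjusted p of 0.05, 111 higher and 36 lower in standard-low. At an unadjusted p under 0.05 there were 31149 contigs, against 27403 for chance alone. The groups did not overlap at 86 of the 147 contigs, 63 higher and 23 lower. Among all contigs 3.245% separated the groups in this way, and chance gives 2.857%. With TMM scaling, which centres the log ratios, 50.28% of contigs had a positive log2 fold change. Other tools called fewer contigs, 32 with DESeq2 and 50 with limma voom, and edgeR called 68 without low-low 2, 58 higher and 10 lower, 97 without standard-low 4, and 207 without standard-low 3, 131 higher and 76 lower. Exchanging low-low 4 with standard-low 1 gave 151 contigs, so the count is not larger than regrouped samples can give. Of the 35 splits of the libraries into 4 and 4, only 3 reached 147 contigs, the real grouping included.

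Repeats made up much of the set. Tandem repeats were 73 of the 147 contigs, or 49.7%, against 1.52% of the table (Fisher's exact p = 5.72e-91), with 53 higher and 20 lower in standard-low. The 37-base family alone gave 57 of them, 46 higher and 11 lower, against 0.702% of the table. Contigs of at most 150 bases were 95 of the 147, and tandem repeats were also more frequent among these short contigs, at 64.2% of those called against 36.1% of all of that length (Fisher's exact p = 3.51e-08). Contigs resembling repeats of primates numbered 21 in the table, of which 14 matched Alu, 6 alpha satellite and 1 the end of an L1 element. Of these, 9 were called, 8 Alu and the L1 end, all higher in standard-low. B1, the rodent counterpart of Alu with 8677 contigs in the table, was not among the called contigs (Fisher's exact p = 0.181). Contigs with any mouse match were under-represented, at 13.6% of the called set against 38% of the table (Fisher's exact p = 7.21e-11). These Fisher tests treat contigs as independent, while alike repeat copies can vary together across the same libraries. Their p-values therefore overstate the evidence and do not measure the spread between samples.

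**Figure D1:**
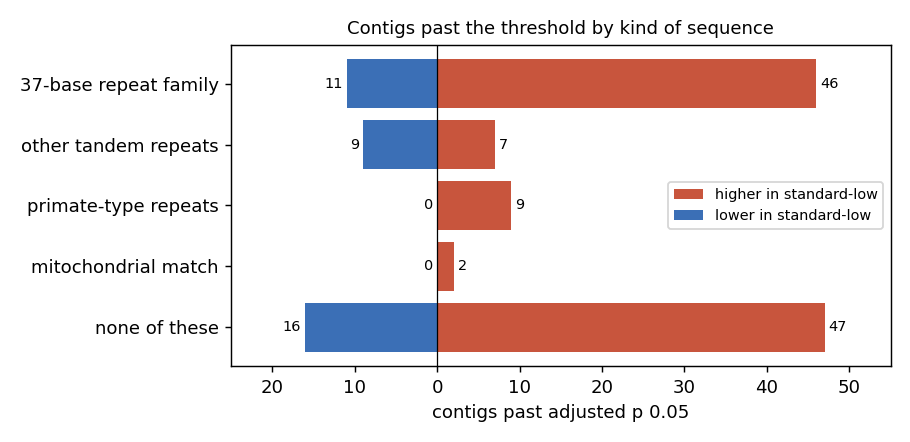
Number of contigs past an adjusted p of 0.05 in the edgeR test by kind of sequence, with those higher in standard-low drawn to the right and those lower to the left. The 37-base family gave 46 higher and 11 lower contigs, and 63 contigs, 47 higher and 16 lower, belonged to none of the named kinds.

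All 12 contigs with the largest increases that also separated the groups belonged to the 37-base family. Contig 465167 had no counts in the 4 low-low libraries and 93 in standard-low, at least 34.3-fold higher when a floor of 3 counts over the group is used (adjusted p = 2.52e-10). Contig 3209397, of 120 bases, reached 9.79 ± 3.91 CPM in standard-low against 0.191 ± 0.158 in low-low (SD, n = 4), a 51.2-fold difference with an edgeR adjusted p of 2.54e-24. Its sequence is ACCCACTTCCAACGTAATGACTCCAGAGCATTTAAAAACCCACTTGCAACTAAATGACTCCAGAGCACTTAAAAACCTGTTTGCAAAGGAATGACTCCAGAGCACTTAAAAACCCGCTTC. Contigs 1510805 and 141505 were 27.1-fold and 24.5-fold higher, on 5 and 4 low-low counts. The other 7, contigs 725913, 147309, 651015, 3051622, 3829378, 589919 and 1646254, had 1 or 2 counts in low-low altogether, with count ratios from 45.4 (95% counting interval 12.2 to 381) to 133 (23.4 to 5290). These intervals and floors cover counting error only. All 12 passed with DESeq2, none passed with limma voom, where their adjusted p ran from 0.168 to 0.891, and 1 passed with voom after cyclic loess.

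The 12 contigs with the largest decreases were more mixed. Contig 4319927, a tandem repeat outside the 37-base family, had 81 counts in low-low and none in standard-low, at least 24.4-fold lower (adjusted p = 4.31e-09). Family contigs 3701970 and 404204 were 10.4-fold and 4.29-fold lower. Further tandem repeats were contig 4435385, 5.61-fold lower, and contig 1117012, 3.64-fold lower. Contigs 4366830, 746465 and 4141235, without a mouse match, were 7.45-fold, 6.1-fold and 6.05-fold lower. Contigs 4397244 and 2466516, also unmatched, were 3.09-fold and 3.04-fold lower. Contig 116652, 3.35-fold lower, had a mouse match of only 29 bases at 17802 bases from Gm13659. With DESeq2 2 of these 12 passed, with limma voom 0, and with the share of counts in the top 1% of contigs as covariate 5. Contig 4397244 passed in 5 of 20 other settings, with an edgeR adjusted p of 0.0558 to 0.256 when 1 library was left out. Contig 2466516 passed in 9 of 20, and contig 404204 had an edgeR adjusted p of 0.977 without low-low 2. Some folds changed when 1 library was left out. Without standard-low 4 they rose to 10.1 for contig 746465, 9.02 for contig 4435385 and 4.57 for contig 2466516. For contig 4141235 the fold rose to 13.8 without standard-low 2 and fell to 4.73 without low-low 2 (edgeR adjusted p = 0.19). It fell to 2.78 for contig 404204 without low-low 2, and to 2.28 for contig 2466516 without low-low 3 (edgeR adjusted p = 0.911).

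The Kcnj4 contig, matched to mouse chromosome 15 from 79484606 to 79484890, was the only one of these 24 contigs within a gene. It had 1.75 ± 0.71 CPM in low-low and 0.504 ± 0.284 in standard-low (SD, n = 4), a log2 fold change of -1.77 ± 0.351 (SE) with an edgeR adjusted p of 0.0127, and it passed in 12 of 20 other settings. The other contigs in genes were singled out after their values were seen. The Oxct2a contig, on mouse chromosome 4 from 123322016 to 123322472, fell from 8.55 ± 0.684 to 4.87 ± 0.351 CPM, a log2 fold change of -0.81 ± 0.152 (adjusted p = 0.00471, past in 16 of 21 settings). The Pcdha10 contig, on chromosome 18 from 36999424 to 36999597, fell from 3.11 ± 0.513 to 1.43 ± 0.457 CPM (adjusted p = 0.0356, past in 8 of 20 settings), and its gene sits in a cluster of close paralogues that can share reads. The Havcr2 contig, on chromosome 11 from 46469670 to 46469804, rose from 1.09 ± 0.486 to 2.93 ± 0.552 CPM (adjusted p = 0.00274, past in 16 of 20 settings), with 138 of its 570 bases aligned to mouse. With DESeq2 the Pcdha10 and Havcr2 contigs did not pass either (adjusted p = 0.111 for Havcr2). Adjusted only over contigs with a mouse match of at least 100 bits, the Kcnj4 and Pcdha10 contigs were no longer called, a setting outside these tallies. Leaving out 1 library also ended calls in these genes in some cases. The edgeR adjusted p of the Kcnj4 contig was 0.0504, 0.408, 0.0942 and 0.199 without low-low 3, low-low 4, standard-low 1 and standard-low 4, and that of the Oxct2a contig 0.0556, 0.0528 and 0.052 without low-low 4, standard-low 1 and standard-low 4. For Pcdha10 it was 0.38, 0.0569, 0.226, 0.366 and 0.238 without low-low 2, low-low 3, low-low 4, standard-low 1 and standard-low 4, and for Havcr2 0.0791 and 0.0549 without low-low 3 and low-low 4. The mouse build and the exon or intron at each position are not given in the sources used here.

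**Figure D2:**
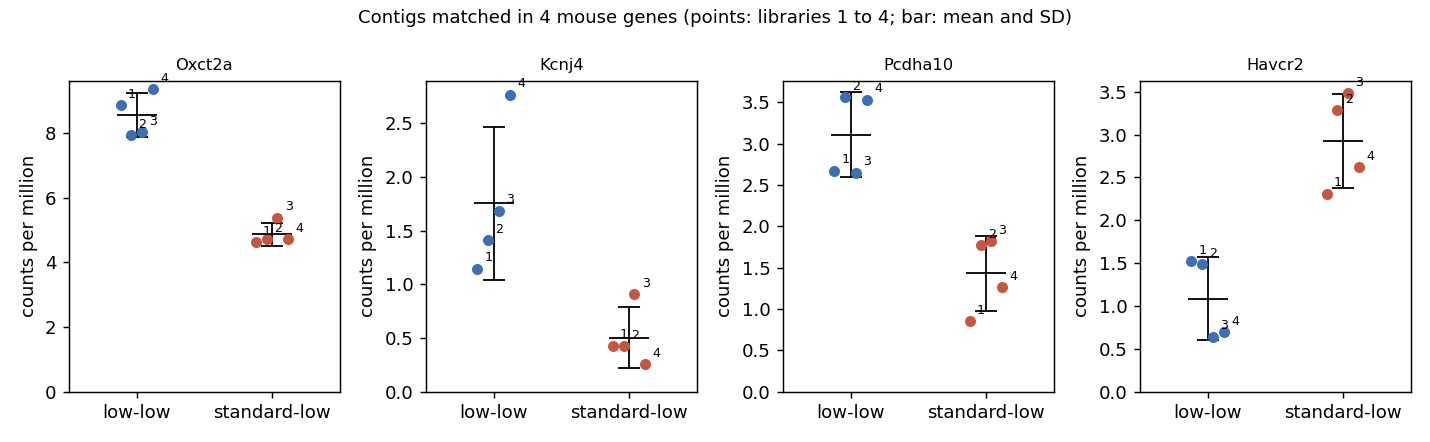
CPM of the contigs matched within Oxct2a, Kcnj4, Pcdha10 and Havcr2, with 1 point per library, numbered by replicate, and bars for the mean and SD of 4 libraries. The groups do not overlap at any of these contigs, and the Oxct2a contig averages 8.55 in low-low and 4.87 in standard-low.

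Mitochondrial contigs were also among those called. The contig in mt-Co1, which encodes a subunit of cytochrome c oxidase, rose from 18.9 ± 2.09 to 33.8 ± 17.6 CPM (adjusted p = 0.00355). The contig spanning mitochondrial positions 9810 to 12180, paired in the table with mt-Tr, rose from 36.9 ± 4.89 to 66.9 ± 30.9 CPM (adjusted p = 4.16e-04). Without standard-low 4 the edgeR adjusted p was 0.774 for mt-Co1 and 0.447 for mt-Tr, and for mt-Co1 it was 0.12 without low-low 3. Neither passed with DESeq2, and summed mitochondrial counts did not separate the groups, at 103, 114, 87.4 and 120 CPM in low-low and 142, 103, 171 and 291 CPM in standard-low (exact permutation p = 0.114). Of the remaining called contigs in genes, those in Gm10369 and Ptpn11 had mouse matches of only 44 and 29 bases, and a pair were Alu-like, so no gene is read from them.

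Genes of the feeding and growth pathways fixed in advance showed no contig past the threshold. The most abundant contig in Pomc, the precursor of the satiety peptide alpha-MSH, had 3.29 ± 0.358 CPM in low-low and 2.65 ± 0.866 in standard-low (SD, n = 4; edgeR adjusted p = 0.917). The contig in Npy, an appetite-stimulating neuropeptide, had 1.21 ± 0.586 and 0.968 ± 0.15 CPM, and that in the leptin receptor gene Lepr 6.92 ± 0.916 and 7.52 ± 1.25. Mc4r, the melanocortin receptor of satiety signalling, had 3.64 ± 0.734 and 3.58 ± 0.773 CPM. The insulin receptor gene Insr had 4.61 ± 0.422 and 3.69 ± 0.77 CPM, the imprinted growth factor gene Igf2 3.16 ± 0.401 and 2.85 ± 0.336, and the de novo methyltransferase gene Dnmt3a 6.88 ± 0.39 and 6.66 ± 1.08. Adjusted p was 0.893 or more for all of these with edgeR and 0 passed with DESeq2 or limma voom. Agrp had no contig, and the Lepr and Insr contigs rest on short mouse matches, of 67 of 1228 and 94 of 1291 bases. Of all contigs in these genes, unadjusted p was under 0.05 for 2 of 14 in Insr, 1 of 9 in Lepr and 1 of 25 in Dnmt3a.

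Across the 8 fixed gene lists, 0 contigs passed over all contigs with edgeR, DESeq2 or limma voom, and 0 genes passed adjusted over the list alone. Lipid metabolism had the lowest camera p as a group. Of its 36 measured genes, 31 had a lower and 5 a higher value in standard-low at their most abundant contig, with a median log2 difference of -0.13 (limma camera adjusted p = 0.428). The same measure was negative for most genes of the table, with a median of -0.07 and 37% positive over 18910 genes, so the signs within a list are read against that. With contigs at any distance from the gene, the lipid list passed camera with an adjusted p of 0.0444, lower in standard-low, and with an estimated correlation the adjusted p in that setting was 0.985. Its lowest contig p was in Lrp1, a lipoprotein receptor, with an adjusted p over the list alone of 0.112. The summed Lrp1 counts were 171 ± 6.02 CPM in low-low and 145 ± 32.6 in standard-low.

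Appetite and energy balance, with 29 measured genes, had 7 of 166 contigs at an unadjusted p under 0.05, and camera gave an adjusted p of 0.847. Summed over its contigs, the leptin signalling gene Stat3 had 34.7 ± 0.423 CPM in low-low and 30.8 ± 3.87 in standard-low (edgeR adjusted p = 0.807). Insulin and IGF signalling, with 27 genes, had 19 of 271 contigs at that level and the same camera adjusted p of 0.847. Its lowest gene sum was Igfbp3, a carrier of insulin-like growth factors, with 6.87 ± 0.478 and 5.1 ± 0.449 CPM and an adjusted p over the list alone of 0.0954. Imprinted genes, with 29 measured, had 10 of 201 contigs at that level, the lowest in Kcnq1 with an adjusted p over the list alone of 0.0604, and the camera adjusted p was 0.847.

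For the DNA methylation machinery 10 of 144 contigs in 17 genes had an unadjusted p under 0.05 (camera adjusted p = 0.899). Hypothalamic development transcription factors had 4 of 62 contigs in 11 of 27 genes (0.932), stress axis genes 8 of 144 contigs in 18 genes (0.847), and neurotransmitter receptor genes 19 of 301 contigs in 28 genes (0.847). Camera gave the direction as higher for the imprinted, methylation machinery, development and stress lists although their medians and means were negative, because it compares a list with the other genes. With contigs inside genes, no list had a camera call to lose with an estimated correlation, where adjusted p was 0.911 or more. Fry, which asks whether the genes of a list move one way on balance, gave adjusted p of 0.283 or more.

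Summed over all contigs within a gene, 1 of 19098 genes passed, Oxct2a, which holds 1 contig and was at 0.569 of its low-low level (adjusted p = 0.0422). At an unadjusted p under 0.05 there were 1151 genes, and the call was lost with limma voom, with a term for the libraries numbered 1 and in 6 of the 8 fits that left out a library. Without standard-low 3 the count was 30 genes, and without standard-low 2 it was 8. This summed test was added after the data were seen. On simulated data 4% of genes with a 1.25-fold change, 54% of those with a 1.5-fold change and 88% of those with a 2-fold change were recovered, and 6 of 18898 unchanged genes were called. Those 6 came beside many called genes with a planted change, and 1 spread was used for all genes. They do not tell how many false calls to expect where few genes change.

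Markers of the cell types that a hypothalamic sample can hold showed 0 contigs past the threshold with edgeR, DESeq2 or limma voom, with 6 of 125 contigs at an unadjusted p under 0.05 for neurons, 7 of 37 for oligodendrocytes and 2 of 54 for microglia. Oligodendrocyte markers had negative differences in 6 of 7 genes with a median of -0.27, and did not pass limma camera (adjusted p = 0.397). Their genes did pass fry's test of change in either direction (adjusted p = 0.0144), and Sox10, a regulator of the oligodendrocyte lineage, had the lowest gene-sum p. Microglial Tmem119 passed as a gene sum adjusted over the list alone (0.0257), at 5.94 ± 0.836 CPM in low-low and 4.05 ± 0.988 in standard-low, but not over all genes (0.807). Astrocyte markers were lower in 4 of 5 genes at their most abundant contig without passing fry (adjusted p = 0.0882). As gene sums, 3 of them were lower and 2 higher. Signs at the most abundant contig are read against all genes, of which 37% were positive. Camera adjusted p was 0.746 for microglia, 0.849 for astrocytes and 0.87 for neuron, endothelial and blood markers, and 0.935 for ependymal, pituitary and thalamus or cortex markers.

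The libraries themselves differed in composition. Primate-type repeat contigs took 73.7, 24.5, 44.1 and 37.2 CPM in low-low and 138, 92.1, 120 and 68.8 CPM in standard-low, a ratio of means of 2.33 (exact permutation p = 0.0571, adjusted p = 0.19). Within them, the 6 alpha satellite contigs took 7.17, 1.48, 2.95 and 2.37 CPM in low-low and 13.5, 7.55, 7.57 and 7.9 CPM in standard-low (exact permutation p = 0.0286, the smallest possible and not adjusted). The 37-base family as a whole took 5846, 7645, 7779 and 8031 CPM in low-low and 6030, 8244, 7895 and 8104 CPM in standard-low (exact permutation p = 0.486). The slopes on CpG per 100 bases were taken from log2 CPM centred per contig on the mean of the 8 libraries, so they sum to 0 and a sign only places a library against that mean. They are lower where CpG-dense contigs take fewer counts, and were -0.03, -0.08, 0.05 and -0.09 in standard-low 1 to 4 against -0.02, 0.06, 0.05 and 0.05 in low-low (exact permutation p = 0.0857). The most abundant 1% of contigs took 5.19% ± 0.0682 of counts in low-low and 4.87% ± 0.33 in standard-low (exact permutation p = 0.114), a difference of -0.32 percentage points that was -0.434 without standard-low 3 (exact permutation p = 0.0286) and -0.174 without standard-low 2 (exact permutation p = 0.257).

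**Figure D3:**
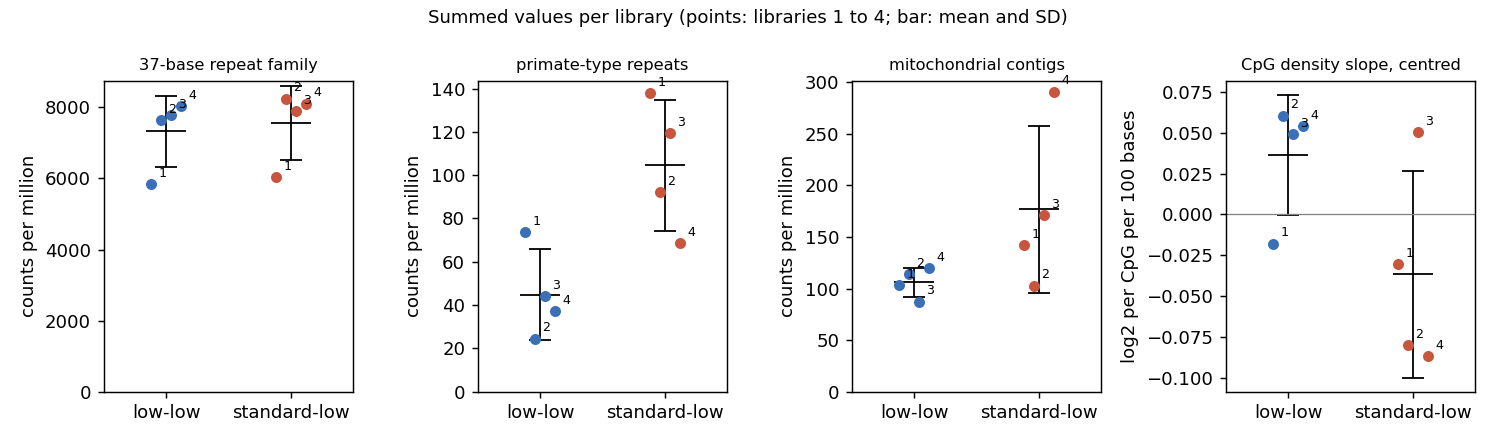
Values per library for the summed CPM of the 37-base repeat family, primate-type repeats and mitochondrial contigs, and for the slope of log2 CPM, centred on the mean of the 8 libraries, on CpG density, with points numbered by replicate and bars for the mean and SD of 4 libraries. Primate-type repeats run from 24.5 to 73.7 in low-low and from 68.8 to 138 in standard-low, and the libraries numbered 1 hold the least of the 37-base family in both groups.

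Low-low libraries resembled one another more than standard-low libraries did. Spearman correlations of log2 CPM over contigs, which are not independent replicates, averaged 0.751 within low-low, 0.684 within standard-low and 0.713 between groups. The mean within groups exceeded that between groups by 0.00461 (exact permutation p = 0.0857), and the sign of this difference turned when any low-low library was left out, to as low as -0.00782. Leaving out a low-low library removes pairs of the more alike group, so this turn says little about single libraries. Within standard-low the correlations of library 2 were low, at 0.63 to 0.677.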

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

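Chosen only after the results were seen were the 40-base test of shared sequence, the splits applied to family contigs with low and high counts, the summed family counts, the B1 ratio, the summed primate-type counts, the mitochondrial correlation and the group test of the CpG slope. The remaining tests of this part, including the splits of the samples for the numbers called, were set before their results were seen.

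A single library stood apart from the other 3 of its group in 13 of 80 groups of values checked, where chance gives about 1 in 20. Low-low 1 had a CpG density slope, centred over the 8 libraries, of -0.02 (-0.0179 unrounded) log2 per CpG per 100 bases, against 0.049 to 0.0605 in the other low-low libraries. Standard-low 1 had 6030 CPM on the 37-base family, against 7900 to 8240 in the others of its group. Several of the repeat contigs had counts in 1 low-low library and none in the other 3, which any single count produces. These were contig 2716599 in low-low 1 (0.306 CPM), contig 725913 in low-low 4 (0.0768 CPM), contigs 147309 and 651015 in low-low 2 (0.0743 CPM each), contigs 3051622 and 3829378 in low-low 1 (0.0764 CPM each) and contig 1646254 in low-low 2 (0.149 CPM). Contig 4366830 was at 1.19 CPM in low-low 2 against 1.68 to 1.77 in the others, and contig 4435385 at 0.922 CPM in low-low 4 against 2.29 to 2.49. Contig 2466516 was at 3.37 CPM in low-low 3 against 1.34 to 1.53, and at 1.27 CPM in standard-low 4 against 0.414 to 0.428.

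Called contigs of the 37-base family lay in both directions, 46 higher and 11 lower in standard-low. The whole family did not differ in summed counts (exact permutation p = 0.486), which excludes nothing for single contigs that go both ways. Presence and absence of repeat variants between animals stays open: of 114 family contigs with at most 3 counts in 1 library and at least 30 in another, 61 (53.5%) showed both within a single diet group, but the bound of 50% set beforehand was too low, as the 35 splits of the libraries gave 79.8% on average and the real grouping the lowest share, with 56.1% to 94.7% in the others, and variants shared by related animals of a group would lower it too. Reads shared between copies stay open, since 87.7% of the called family contigs share a 40-base word with another contig, against 86.7% of other family contigs (Fisher's exact p = 1). The bound set beforehand on 50-base words was not applied, because 0% of the called contigs and only 2% of any contigs share a word of that length, so the table cannot show it, and a methylation difference between the diets also remains untested.

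Primate-type repeat contigs were higher in standard-low, at 104.6 ± 30.4 against 44.9 ± 20.9 CPM (SD, n = 4). The rodent B1 contigs did not rise, with a ratio of group means of 1.001, and so gave no sign of capture or depth acting on interspersed repeats. They needed a B1 match over only 20% of the contig, at any identity. The ratio therefore cannot exclude such an effect on contigs made mostly of repeat. Human DNA in all 8 libraries, at a higher share in standard-low, is a candidate explanation. The 21 contigs kept nearly one ratio between libraries (chi-square per degree of freedom 1.31), as a single source would give. No other set of contigs was compared on this measure, so the value does not set human DNA apart from other causes. A methylation difference in sand rat DNA would need these primate-type sequences in the sand rat genome, for which no assembly was used here, and the summed counts do not decide it (exact permutation p = 0.0571, and 0.0286 for the alpha satellite contigs alone), since a higher share of human DNA would raise them too.

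The CpG density slope, centred over the 8 libraries, was on average 0.07 lower in standard-low than in low-low, and the groups overlapped, with standard-low 3 at 0.05 and low-low 1 at -0.02. Weaker capture of methylated DNA may be the source, and would leave more mitochondrial background, but the relation of mitochondrial CPM to the slope was not clear over 8 libraries (Pearson r = -0.464, exact permutation p = 0.25, Spearman rho = -0.143, exact permutation p = 0.752). It rests on standard-low 4, without which r was 0.174, and with standard-low 3 also left out r was -0.122. GC content stays open as well, since 72.2% of the group difference in slope was left with GC in the regression. A methylation difference between the diets cannot be told apart from these (exact permutation p of the slope 0.0857), because capture strength and methylation act on the same contigs.

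Chance cannot be excluded for the number of contigs called. Of the 35 splits of the 8 libraries into 4 and 4, 3 gave at least the 147 contigs of the real grouping, itself included. The highest other gave 151, with low-low 4 and standard-low 1 exchanged, and the next 149, with low-low 1 and standard-low 3 exchanged. Both exchange 1 library of each group and so keep most of the real grouping. For gene sums 4 of the 35 splits gave at least the 1 gene of the real grouping, and the highest other gave 21, with low-low 1 and standard-low 3 exchanged. For gene lists the real count was 0, so all 35 of 35 splits reached it, and the highest other gave 1.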

How the results depend on the processing

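Tests chosen after the data were seen were those without repeat contigs, with strong mouse matches alone, with offsets or a term for the libraries numbered 1, the gene sums and the lists at any distance. The number of called contigs depended strongly on the tool and on the kinds of contig kept. Against 147 contigs, 111 higher and 36 lower, DESeq2 gave 32 (29 and 3), limma voom 50 (42 and 8), voom after cyclic loess 68 (60 and 8), and a mean of at least 30 counts 50 (43 and 7), of which 44 were shared. The share of higher calls was 75.5% with edgeR, 84% with limma voom and 88.2% with voom after cyclic loess, and with the top 1% share as covariate 19 contigs were lower. Without tandem repeats 56 were called (46 and 10), and without tandem, primate-type and mitochondrial contigs 44 (35 and 9). Among contigs with a mouse match of at least 100 bits 5 were called (4 and 1). Of these same contigs 7 (4 and 3) had been called with adjustment over all contigs. The calls lost were those in Kcnj4 and Pcdha10, so these depended on which contigs were adjusted together. Each of these sets had fewer contigs to adjust over. Filters at a mean of 5 or 10 counts, or none, removed no contig and so test nothing. Other causes were not tested.

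Leaving out each library in turn gave 68 to 207 contigs, 58 to 155 higher and 10 to 76 lower. All 3 were lowest without low-low 2, the total and the lower calls were highest without standard-low 3 and the higher calls without low-low 1, and 97 contigs were called without standard-low 4. Size factors of DESeq2, library size and upper quartile scaling changed the share of positive log2 fold changes from 50.28% to 50.71%, 52.25% and 48.49%, and leaving out libraries gave 49.89% to 50.46%.

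The difference in total counts ranged from -1442000 to -1107000 with a library left out, and the exact permutation p then rose to 0.0571 without standard-low 1, 2 or 4. The share in the top 1% of contigs differed by -0.434 to -0.174 percentage points, with an exact permutation p of 0.0286 without standard-low 3 and 0.257 without standard-low 2. The share of contigs detected differed by -0.000623 to 0.00514 points, negative without low-low 3. Similarity within over between groups ranged from -0.00782 to 0.0212, negative whenever 1 low-low library was left out, and with an exact permutation p of 0.0286 without standard-low 3. The sign follows in part from which group loses pairs, since low-low pairs were more alike.

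With contigs at any distance 1 gene list passed camera, lipid metabolism at an adjusted p of 0.0444, against 0 otherwise, and no marker list passed. With an estimated correlation its camera adjusted p in that setting was 0.985. Gene sums gave 2 genes with their own factors, 2 with DESeq2, 0 with limma voom, 0 with a term for the libraries numbered 1, and 0 to 30 when libraries were left out. Whether the replicate numbers pair the samples is not settled. Deviations from the group means correlated by 0.013, 0.0313, 0.0273 and -0.00953 for numbers 1 to 4. Low-low 2 and 3 correlated best with the standard-low library of their own number, and low-low 1 and 4 did not. The libraries numbered 1 had the highest Spearman correlation between groups, at 0.742. With the replicate block 206 contigs (153 higher and 53 lower) and 3 gene sums were called.

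For the 24 contigs named by rule, 377 of 482 alternative fits kept direction and call, 105 kept direction but not the call, and 0 reversed. A reversal could hardly occur, because these contigs were chosen in the same counts for large folds and groups without overlap. For the 7 fixed genes with a contig all 146 fits left them uncalled. Simulated counts had the depth, group size and number of contigs of these data, with a spread set by abundance alone. In them 1.5-fold changes were recovered at 0% of contigs and 2-fold changes at 38%, and depth was not varied separately.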

Other observations

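The gene sums and the counts per library in this part were chosen after the data were seen.

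Beyond Oxct2a, no gene sum passed over all 19098 genes with edgeR, and the genes named here were picked from those with the lowest p. Pold2, a subunit of DNA polymerase delta, had 25.4 ± 1.29 CPM in low-low and 19.7 ± 2.15 in standard-low (SD, n = 4; edgeR adjusted p = 0.807). Uts2r, the urotensin receptor gene, had 16.1 ± 0.905 and 11.7 ± 2.04 CPM, and Atg2a, a lipid transfer gene of autophagy, 50.9 ± 1.31 and 41.5 ± 5.73 CPM. In the other direction Kcnmb4, a neuronal subunit of the BK potassium channel, had 15.8 ± 1.13 and 20.3 ± 1.63 CPM. Of the 30 genes called without standard-low 3, 28 were lower in standard-low, and they included Pold2, Uts2r, Atg2a, Lrp1, Pxn and Plxnb2. Gene sums as a whole lay low in that fit, with 38.73% positive, against 41.38% with all libraries and 50.72% with factors from the gene sums. Standard-low 3 also has a CpG density slope, centred over the 8 libraries, of 0.05, above the -0.03, -0.08 and -0.09 of the other standard-low libraries.

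Among the called contigs, 6 were at more than 8 times the level of every other library in standard-low 4, and no other contig of the table met that bound. A further 6 called contigs outside the named repeats followed the mitochondrial profile across libraries with a correlation above 0.9, against 408 in the whole table, and 13 followed the primate-type profile, against 791. Those profiles are themselves higher on average in standard-low, so contigs called higher there match them more often by selection.

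For 12 of the 57 called family contigs, every library of the lower group held at most 3 counts.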
